A study of Homo sapiens with 15 samples.

How the data were processed

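Gene expression was measured on 2-colour microarrays in 15 samples of THP-1, a human monocytic leukaemia line, and of the IkB mutant lines A3 and A12 derived from it. Per the labels, each sample was labelled with Cy5 and hybridised against a Cy3-labelled pool of all samples. Each of the 3 lines was measured in 5 conditions: unstimulated, after PMA and vehicle at day 5 and day 8, and after PMA and oxidised LDL (oxLDL) at day 5 and day 8. PMA was given at 100 nM for 24 hours. The growth protocol describes PMA for all cells and the extract protocol names endothelial cells, whereas the titles name unstimulated samples and THP-1 lines. The titles were followed. There was 1 array for each line and condition, so no condition of a line was replicated.

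The value table the authors deposited holds log2 ratios of sample over reference for 18659 probes. The submitters' processing notes name limma, with no version and no role. Each of the 15 columns was set against the ratio columns of the scanner table, and each equalled the log2 of exactly 1 of them within 0.00589. The scanner table's 120 columns of array values carry array numbers that no label gives. The match by value was used for scale and direction and not to assign these columns to samples, so no comparison used the scanner table. Besides this match, its channels had been looked at before the fits were settled, which raised doubts about the PMA-treated parental arrays before the alternatives that drop an array or add a term were chosen. No value from that look is reported. Its intensities, background and dye balance therefore entered no result, and the planned background correction, loess, print-tip loess, average-intensity quantile scaling, dim-probe filter and intensity trend were not run. The authors' log2 values were used in place of ratios normalized here. Scale and direction followed from this match and the dyes in the labels, and the authors' centring within an array was not given in the sources used here. Column medians lay between -0.0375 and 0.0607.

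The authors left values empty on every array, and arrays held between 7494 and 18600 measured probes. A probe was tested where every term of the fit could be estimated and a residual degree of freedom was left. Of the probes, 3925 were measured on all arrays. Probe names came from the platform annotation with symbols updated through gene identifiers: 13926 probes had 1 symbol, 26 had several and 4707 had none. Probes with several symbols were not named. Where a gene had several probes, the one measured on most arrays, or of equals that with the lowest probe number, stood for it in lists and named genes, since the mean intensity planned for this choice was not used here.

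Differences were tested with limma version 3.58.1 in R version 4.3.3, with lmFit and eBayes and Benjamini-Hochberg adjustment over all tested probes, called at an adjusted p under 0.05. The additive fit had terms for line and condition over all 15 arrays, with 8 residual degrees of freedom. It gave PMA against unstimulated, oxLDL against vehicle, mutants against parental, day 8 against day 5, and A12 against A3. A fit with a mean per line and state plus day, with 5 residual degrees of freedom, gave the differences between lines in the response to PMA or oxLDL and in oxLDL-loaded cells. The lines stood in for replicates, so p-values measure the spread between these arrays after line and condition, not between independent cultures. Contrasts were fitted as coefficients of their own, so that missing values were handled exactly.

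Lists of genes, 25 in all, were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, for lists with at least 3 tested genes, which were 23. Metallothioneins and epithelial markers had fewer and were not tested. The same test was run with a correlation estimated from the residuals of members measured on every array. A negative estimate was taken as 0, which is less strict than the preset. Named genes followed a rule also fixed before the data were examined: up to 10 of the largest rises and falls past the threshold with the same direction in each line (up to 5 for other comparisons), the 5 lowest p in a direction where fewer than 5 passed, 2 to 4 members of each described list, and a fixed set of key genes.

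The fits reported as results are those fixed before the data were examined. The array of parental cells with vehicle at day 5 and the PMA-treated parental arrays were found to differ from the others when the values were inspected. Counts under 18 other fits, including fits that drop that array or add a term for PMA-treated parental arrays, had been seen before it was settled that the fits fixed in advance would stand as the reported ones. The alternatives that drop the array, add the term, turn the sign of 3 arrays, restrict the probes, use unstimulated cells alone, pair arrays within a line or use a robust variance prior were therefore chosen after seeing the data. Other alternatives, fixed before the data were examined, were median centring, scale normalization, array weights, a minimum log2 change of 1, gene means, leaving out each array and each line, each mutant line alone, line as a random block, each day alone, the other fit for each comparison, fry in place of camera, and list tests on gene means. The run with fry used only probes measured on all arrays, so its lists could hold fewer members than those tested with camera.

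The scripts were tested on simulated arrays with the real pattern of missing values and the estimated spread, in which 200 of 9382 probes were changed. For oxLDL against vehicle, 4% of the probes changed by 1 on the log2 scale and 54% of those changed by 2 were recovered. For PMA against unstimulated the shares were 2% and 39%. The simulated errors were independent, with the same spread on every array for a probe. In the data the PMA-treated parental arrays stood apart, so these shares need not hold there.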

Results

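The data were log2 ratios of each sample over a common reference pool on 15 arrays, 5 of each line. Parental arrays held 16115, 10700, 16124, 16597 and 18600 measured probes, from unstimulated cells through vehicle at day 5 and day 8 to oxLDL at day 5 and day 8. Arrays of the A3 line held 13817, 7800, 8436, 7494 and 9113 probes, and those of the A12 line 9818, 8362, 8580, 8540 and 8074, in the same order. The number of arrays limits the precision of every value below, and no condition of a line was replicated.

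Arrays of the mutant lines correlated with one another across probes at a median r of 0.784, and the unstimulated parental array correlated with them at a median r of 0.781. The parental vehicle day 5 array had correlations between 0.0282 and 0.0877 with every other array. The other 3 PMA-treated parental arrays correlated at a median r of 0.652 with one another and at a median r of -0.325 with the mutant arrays, reaching -0.559. The labels state the same dyes for all arrays, so the direction was kept, and each comparison was also run with the sign of these 3 arrays turned. Genes are not independent replicates, and these correlations are across genes.

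**Figure D1:**
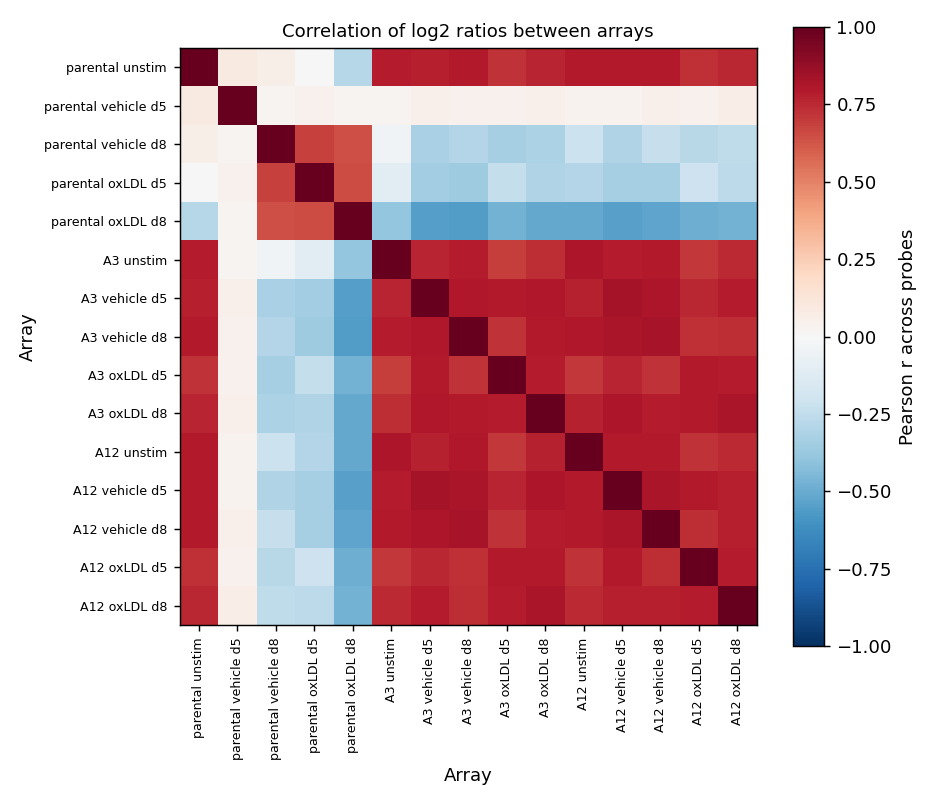
Pearson correlation across probes between the log2 ratios of each pair of the 15 arrays, with arrays on both axes and colour for r. The parental vehicle day 5 array lies near 0 with every other array, and the other 3 PMA-treated parental arrays lie at a median of -0.325 with the mutant arrays.

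The IkB genes were examined first, as the family the mutation is in. The probe for NFKBIA, which encodes IkB alpha, read 1.34 in unstimulated parental cells, 1.19 in unstimulated A3 cells and 1.58 in unstimulated A12 cells. In PMA-treated cells it read -2.60, -2.41 and -2.03 on the parental arrays that measured it, and between 0.69 and 2.41 on the 8 mutant arrays. NFKBIE read -0.06, -0.61 and -0.89 in unstimulated parental, A3 and A12 cells. NFKBIB was measured on 5 arrays and was not tested. The labels do not say which part of which gene was altered, so these probes do not check the mutation.

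The comparison of oxLDL with vehicle asked what lipid loading changed in macrophages. GBE1, the glycogen branching enzyme, rose by 2.15 ± 0.23 (log2, SE, adjusted p = 0.0115). MME, a membrane metalloendopeptidase, rose by 2.18 ± 0.34 (adjusted p = 0.0392), and the cation-transporting ATPase ATP13A3 rose by 1.81 ± 0.24 (adjusted p = 0.0233). The membrane protein MS4A4A fell (adjusted p = 0.0346), with changes of -1.30 in parental, -1.95 in A3 and -2.73 in A12 cells. POLA1, the catalytic subunit of DNA polymerase alpha, fell by 1.71 ± 0.28 (adjusted p = 0.0436) and COPZ2 fell by 1.25 ± 0.19 (adjusted p = 0.0346). Each moved in the same direction in all 3 lines, which the rule for naming required.

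Among further rises in every line were those of PNLIPRP1 (2.22), RAB23 (1.75), CSGALNACT2 (1.69), BTBD2 (1.68), IL1RL2 (1.68), SPIRE1 (1.53) and BCAT1 (1.48). GFPT1, named after its values were seen, passed at a probe that does not stand for the gene here (1.89, adjusted p = 0.0233), and its standing probe changed by 1.17 (adjusted p = 0.214). DDIT3, a transcription factor of the ER stress response, rose by 1.10 ± 0.17 (adjusted p = 0.0392). It was the 1 member of its list of 12 tested genes to pass, over all probes and adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0927). In all, 19 probes rose and 5 fell among 9382 tested by limma. HNRNPD, SLC38A10, SRSF2, FLOT1 and CD244 had the lowest p among falls that did not pass, with adjusted p from 0.0520 to 0.0618, though FLOT1 changed by -3.31 in A12, -0.19 in parental and 0.03 in A3 cells. A second probe of HNRNPD changed by -0.2, against -2.03 at its standing probe. SLC28A3, ALOX12, NDUFB4 and ENTPD4, named after their values were seen, also passed. They changed by 6.54, 5.90, 3.59 and 3.06 in parental cells, where the vehicle day 5 array enters the mean, and by at most 2.01 in the mutant lines where measured. Singled out in the same way, the probe 888239 with no gene name here changed by 6.21 in parental, 1.58 in A3 and -0.28 in A12 cells, and among the falls the unnamed probe 878857 (-4.09) and FRMD4A (-4.80) had their change in A3 cells, against -0.32 and -0.22 in parental cells.

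**Figure D2:**
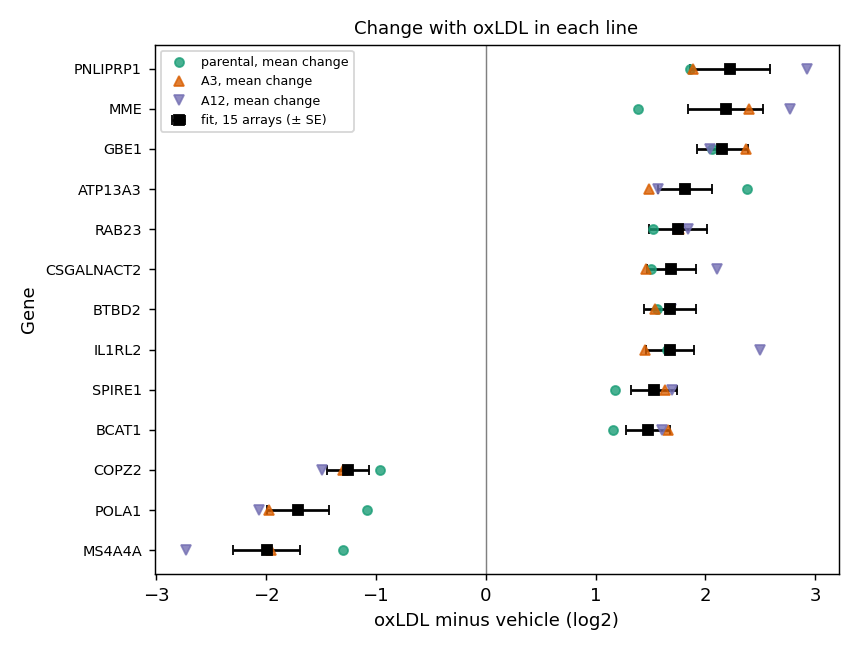
Change with oxLDL (log2, oxLDL minus vehicle) of the genes that passed the threshold with the same direction in every line, as the naming rule required. Squares and bars show the additive limma fit and its SE over 15 arrays, and other symbols show the mean change within each line. GBE1 changed by 2.06 in parental, 2.37 in A3 and 2.04 in A12 cells.

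Cell cycle genes fell as a list with oxLDL over the 3 lines together: 22 of 27 tested members were lower, with a median of -0.74 (camera adjusted p = 0.000277). Not every line need share this: the member MCM6 changed by 0.677 in parental, -1.125 in A3 and -1.769 in A12 cells. The change in mutants minus that in parental cells was below 0 for 21 of 24 members, with a median of -1.28. That difference had a camera adjusted p of 0.126 with an estimated correlation. For the fall over the 3 lines together, the list's adjusted p was 0.387 with an estimated correlation. No member passed over all probes and 6 fell when adjusted over the list alone, among them CCNB1 (-1.02 ± 0.24), CENPF (-1.47 ± 0.35), PCNA (-1.32 ± 0.33) and MCM7 (-1.16 ± 0.28). Genes of the NRF2 response to oxidative stress rose as a list, with 11 of 12 members higher and a median of 0.68 (camera adjusted p = 0.00153, and 0.00132 with an estimated correlation). GCLM (1.32 ± 0.34) and TXNRD1 (1.19 ± 0.30), which serve glutathione and thioredoxin metabolism, rose when adjusted over the list alone, and no member passed over all probes. The list of myeloid progenitor and granule genes fell, with 8 of 8 members lower and a median of -0.87 (camera adjusted p = 0.0389, and adjusted p = 0.361 with an estimated correlation). Its members PRTN3 (-1.02 ± 0.37) and CTSG (-1.22 ± 0.57) passed neither adjustment. This list did not pass (adjusted p from 0.0557 to 0.112) without parental vehicle day 5, A3 vehicle day 8, A12 vehicle day 5 or any 1 of the oxLDL arrays of A3 and A12.

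Key genes of lipid handling did not pass with oxLDL in this fit. The scavenger receptor CD36 changed by 2.67 ± 1.21 (adjusted p = 0.480), the fatty acid binding protein FABP4 by 0.98 ± 0.30 (adjusted p = 0.244), the cholesterol exporter ABCG1 by 1.28 ± 0.51 (adjusted p = 0.384) and the lipid droplet protein PLIN2 by 0.94 ± 0.50 (adjusted p = 0.578). CXCL8 changed by 1.36 ± 0.38 (adjusted p = 0.210), NFKBIA by 0.73 ± 0.59 (adjusted p = 0.728) and HMOX1 by 0.46 ± 0.21 (adjusted p = 0.468). TNF, CCL2, BCL2A1 and MPO lacked values on arrays that the terms of the fit need and were not tested, and BIRC3 and MKI67 had no named probe here.

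The oxLDL count moved with the parental arrays and with single mutant arrays. In the mutant lines alone 188 probes rose and 201 fell, and 18 of the 24 probes were among them. There FABP4 (1.36, adjusted p = 0.00962), ABCG1 (1.21, 0.0175), NFKBIA (1.04, 0.0246) and CXCL8 (1.68, 0.0353) passed. CD36 (2.495, adjusted p = 0.0845), HMOX1 (0.0670) and PLIN2 (0.168) did not. An alternative chosen after its counts were seen left out the parental vehicle day 5 array and had a term for PMA-treated parental arrays. In it 194 rose and 188 fell, 19 of the 24 among them. CD36 (2.36, adjusted p = 0.0418), FABP4 (1.22, adjusted p = 0.00885), CXCL8 (1.69, adjusted p = 0.0157) and NFKBIA (0.89, adjusted p = 0.0350) passed. PLIN2 (adjusted p = 0.0655), ABCG1 (0.145) and HMOX1 (0.192) did not pass in it. With vehicle and oxLDL arrays of a line and day taken as pairs, an alternative also chosen after seeing the data, 15 probes rose and 1 fell among 7371, and 6 of the 24 were among them. GBE1, CSGALNACT2, BCAT1 and POLA1 passed there, and PNLIPRP1, MME, ATP13A3, RAB23, BTBD2, IL1RL2, SPIRE1, MS4A4A and COPZ2 did not, with adjusted p from 0.0506 to 0.0758. With the sign of 3 parental arrays turned, 2 probes passed. Leaving out 1 array gave between 0 probes, without parental oxLDL day 8, and 118, without unstimulated parental cells. It gave 2, 1 and 5 without vehicle day 8, oxLDL day 5 and oxLDL day 8 of A3, and 3, 4 and 1 without those of A12. By limma 0 passed without the A3 line and 0 without the A12 line, where 447 and 450 had an unadjusted p under 0.05.

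The comparison of PMA-treated with unstimulated cells asked what differentiation changed. The titles call 1 sample of each line unstimulated, whereas the growth protocol describes PMA for all cells, and the titles were followed. Lists of macrophage function rose: the lysosome list had 17 of 20 members higher with a median of 0.46 (camera adjusted p = 0.00522, and 0.0232 with an estimated correlation), and macrophage maturation had 12 of 15 higher with a median of 0.39 (adjusted p = 0.0252, and 0.0232 with an estimated correlation). Metalloproteinases and inhibitors rose as well, with 7 of 10 higher and a median of 0.67 (adjusted p = 0.00556, and 0.00961 with an estimated correlation). The estimated correlation was 0 for maturation and for metalloproteinases, below the preset 0.01, so it was no stricter test there. With fry in place of camera, on probes measured on all arrays only, 0 lists passed for PMA. No member of these lists passed over all probes. Leaving out 1 array ended these calls: lysosome without unstimulated parental cells (adjusted p = 0.148) or parental vehicle day 8 (0.0577), metalloproteinases without parental vehicle day 8, parental oxLDL day 5, unstimulated A3, unstimulated A12 or A12 vehicle day 5 (0.0586 to 0.284), and maturation without any 1 of the unstimulated arrays, of the vehicle day 5 arrays or parental vehicle day 8 (0.0522 to 0.211).

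Adjusted over the list alone, the lysosomal protease CTSH (1.46 ± 0.32), the integrin ITGAM (1.05 ± 0.27), MMP14 (4.26 ± 0.68), MMP7 (1.10 ± 0.31) and TIMP2 (1.44 ± 0.44) rose. The list of PPAR targets and lipid storage rose with a median of 0.54 over 10 members (camera adjusted p = 0.00499, and adjusted p = 0.332 with an estimated correlation), and FABP5 (2.33 ± 0.41) and CPT1A (1.69 ± 0.40) passed over the list alone. Its key genes were higher in the parental line alone: PLIN2 changed by 2.65 in parental, -0.77 in A3 and -0.13 in A12 cells. FABP4 changed by 1.73, -0.10 and -0.14 in the same order. Both parental changes set the vehicle day 5 and day 8 arrays, which stand apart from the mutant arrays, against the unstimulated array. A difference of the parental line therefore cannot be told apart from those arrays. The interferon response list fell, with 11 of 14 members lower and a median of -0.72 (adjusted p = 0.0169, and adjusted p = 0.374 with an estimated correlation). Its members MX2 (-1.17 ± 0.51) and IFI35 (-0.75 ± 0.26) passed neither adjustment. Without unstimulated parental cells the PPAR list (adjusted p = 0.247) and the interferon list (0.778) did not pass, nor did the latter without parental vehicle day 8 (0.0586) or A3 vehicle day 5 (0.0685).

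**Figure D3:**
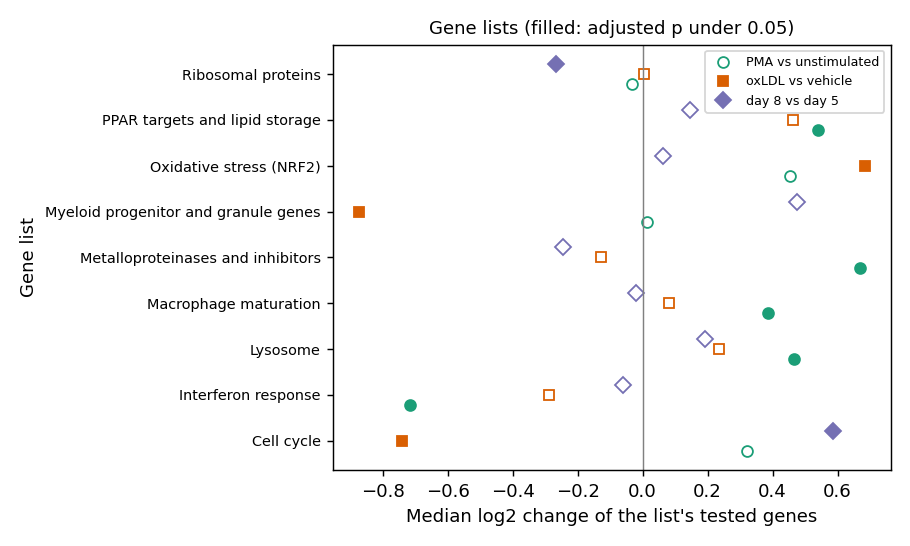
Median log2 change of the tested members of each gene list (horizontal axis) that passed in at least 1 of 3 comparisons, with filled symbols for an adjusted p under 0.05 by camera at the preset correlation. Cell cycle genes have a median of -0.74 with oxLDL and 0.58 at day 8 against day 5.

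With PMA, 1 probe rose and 1 fell among 9382 tested by limma, and 827 had an unadjusted p under 0.05. Neither has a gene name here, and both are singled out after their values were seen: probe 878857 rose by 4.47 ± 0.32 and probe 888239 changed by -7.55 ± 0.56. The first changed by 4.73 in A3 cells, 0.32 in parental and -0.35 in A12 cells. Among genes that did not pass, PRR5L (3.54 ± 0.34), CYP19A1 (2.45 ± 0.33), S100A9 (2.29 ± 0.33), SLC8A1 (3.32 ± 0.48) and FRMD4A (5.41 ± 0.47) had the lowest p among higher values, with adjusted p from 0.0671 to 0.0698. A second probe of PRR5L went the other way, at -0.16. SLC28A3, VEZF1, NDUFB4, FOXP1 and MAP1B had the lowest among lower values, with adjusted p from 0.0698 to 0.173. FRMD4A changed by 5.96 in A3 and 0.37 in parental cells and had no value in A12 cells. SLC28A3 changed by -6.53 in parental, -1.18 in A3 and 1.43 in A12 cells, and NDUFB4 by -2.54, 0.20 and 0.61. CD14 changed by 0.39 ± 0.40 (adjusted p = 0.745) and HMOX1 by 0.95 ± 0.25 (adjusted p = 0.358). The fit with a mean per line and state gave 114 probes, and the mutant lines alone gave 0 by limma, with 889 at an unadjusted p under 0.05.

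The comparison of the IkB mutant lines with the parental line asked what the mutation changed. Over all conditions 1127 probes were higher and 1508 lower in the mutants. MYO9A was higher by 11.31 ± 2.04 (adjusted p = 0.00910), BCL2L11 by 10.31 ± 2.02 (adjusted p = 0.0103) and FABP3 by 9.03 ± 2.02 (adjusted p = 0.0162), and PRL was lower at -12.32 ± 2.26 (adjusted p = 0.00958) and TBL1X at -11.04 ± 1.57 (adjusted p = 0.00770). Values in unstimulated cells were smaller, from 1 parental array that is assumed to vary like the others: MYO9A differed by -0.44, BCL2L11 by -0.12, FABP3 by -0.47, PRL by -0.51 and TBL1X by -1.27, with adjusted p of 0.9999 for each. In unstimulated cells alone, an alternative chosen after its counts were seen, limma called 0 of 7420 probes, and 210 had an unadjusted p under 0.05, which does not show that the unstimulated lines were alike.

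Other large differences of this kind were higher values of RGPD1, MED15, HCRP1, ATXN7L1, CALCOCO1, C19orf25 and TRIM15 and lower values of H2BC15, TRPM7, OR7E47P, GRIN2B, ZNHIT6, GPC1, PDE6C and LINC00563. A second probe of ZNHIT6 went the other way, at 1.61. PMA-treated parental cells were measured only on the arrays that stand apart, so whatever sets those arrays apart and the difference between the lines cannot be told apart.

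NF-kB target genes were higher in the mutants as a list, with 25 of 26 members higher and a median of 1.31 (camera adjusted p = 0.000293, and adjusted p = 0.558 with an estimated correlation). Over all probes 11 members rose and over the list alone 12, among them IL1B (3.68 ± 0.62), the NF-kB inhibitor TNFAIP3 (2.27 ± 0.39), GADD45B (2.54 ± 0.53) and NFKBIA (2.90 ± 0.58). Against the single unstimulated parental array, IL1B differed by 0.17 and NFKBIA by 0.04 in unstimulated cells. The interferon response list was higher, with 14 of 14 members and a median of 1.01 (adjusted p = 0.0318, and adjusted p = 0.499 with an estimated correlation). Over all probes 5 members rose and over the list alone 6, IFIT3 (1.88 ± 0.40) and MX2 (1.71 ± 0.40) among them. Both lists lost their direction with the sign of the 3 arrays turned. They also had the other sign without parental vehicle day 5 and with a term for PMA-treated parental arrays. That fit leaves the difference in unstimulated cells, from the single unstimulated parental array. The interferon list did not pass without parental vehicle day 8, parental oxLDL day 8 or either A12 vehicle array (adjusted p from 0.0546 to 0.122). CD36 (-4.67 ± 1.20), PLIN2 (-1.86 ± 0.48), MSR1 (-1.46 ± 0.28) and HMOX1 (-1.16 ± 0.20) were lower and ABCG1 (1.83 ± 0.48) was higher past the threshold. In unstimulated cells CD36 differed by 1.06, PLIN2 by 0.84, MSR1 by -0.22, HMOX1 by -1.18 and ABCG1 by 0.22, none past the threshold.

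In oxLDL-loaded cells 987 probes were higher and 1532 lower in the mutants among 7420. NFKBIA (4.07 ± 0.33), IL1B (4.81 ± 0.48) and GADD45B (3.42 ± 0.32) were higher, and 12 of 20 NF-kB target genes rose over all probes and 13 over the list alone (camera adjusted p = 3.27e-06, and adjusted p = 0.273 with an estimated correlation). Of 24 cell cycle genes 11 fell by both adjustments, MCM6 (-4.44 ± 0.29) and CDC20 (-4.53 ± 0.30) among them (camera adjusted p = 0.0105, adjusted p = 0.279 with an estimated correlation, and adjusted p = 0.0660 without parental oxLDL day 5). The largest differences were those of MYO9A, CALCOCO1, BCL2L11, ALDH1A2 and TRIM15, which were higher, and of PRL, TBL1X, H2BC15, OR7E47P and GRIN2B, which were lower. All parental arrays in this comparison are among those that ran against the mutant arrays, so line and array cannot be told apart. With the sign turned 145 probes were higher and 444 lower.

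The response to PMA differed between mutant and parental cells at 115 probes that were higher and 311 that were lower among 7420. Of 20 NF-kB target genes 5 were higher over all probes and 7 over the list alone (camera adjusted p = 0.000106, and adjusted p = 0.239 with an estimated correlation), CCL3 (3.71 ± 0.50) and GADD45B (3.81 ± 0.56) among them. The receptors CD36 (-7.76 ± 0.80) and VLDLR (-6.76 ± 0.51) were lower by both adjustments, and the list of scavenger and lipoprotein receptors was lower (adjusted p = 0.0202, and adjusted p = 0.0577 with an estimated correlation). The interferon response list was higher in all 11 members (adjusted p = 0.0367, and adjusted p = 0.180 with an estimated correlation), with IFIT3 (2.88 ± 0.61) past both adjustments. CD36 changed by 7.40 with PMA in parental, 1.70 in A3 and -2.08 in A12 cells. The parental side of this difference sets an array of the common pattern against the vehicle day 8 array, which ran against the mutant arrays, and the vehicle day 5 array, which was unlike every other, so it too cannot be told apart from the arrays. With array weights 4 probes were higher and 4 lower, with the sign of the 3 arrays turned 2 were higher and 21 lower, the NF-kB list turned (adjusted p = 0.939) and NFKBIA stood at -1.64, and leaving out 1 array gave between 140 probes, without A12 vehicle day 8, and 1334, without parental vehicle day 8. Without parental vehicle day 8 the NF-kB, receptor and interferon lists did not pass (adjusted p of 0.636, 0.213 and 0.692), nor did the receptor list without parental or A12 vehicle day 5 (0.102 and 0.0932) or the interferon list without A3 vehicle day 8 (0.0783).

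The response to oxLDL differed between mutant and parental cells at no probe by limma among 7420, where 480 had an unadjusted p under 0.05. Cell cycle genes had lower values of this difference, with 21 of 24 below 0 and a median of -1.28 (camera adjusted p = 1.10e-06, and adjusted p = 0.126 with an estimated correlation). MCM6 (-2.12 ± 0.41), PCNA (-1.49 ± 0.38) and CDC20 (-1.63 ± 0.42) passed over the list alone and none passed over all probes. NF-kB target genes had higher values, with 19 of 20 above 0 and a median of 0.65 (adjusted p = 0.0139, and adjusted p = 0.547 with an estimated correlation), and no member passed either adjustment. The NF-kB list did not pass without parental vehicle day 5 (adjusted p = 0.940), parental oxLDL day 5 (0.0605), A3 oxLDL day 8 (0.0956) or unstimulated A12 cells (0.0556), and the cell cycle list did not pass without parental vehicle day 8 (0.135). By the probe that stands for each gene, ST7L, ID1, EIF2AK2, BAHD1 and PPP1R13L were the genes with the lowest p among higher values and PBK, CA4, SMC4, MCM6 and TCF20 among lower ones, each at an adjusted p of 0.673. Other probes of ERCC1 (-2.17) and ATP6AP1 (-4.92), singled out after their values were seen, had p as low, while their standing probes had values of 0.30 and -0.56. The mutant lines differed in the higher genes: with oxLDL, ST7L changed by -0.72 in A3 and 7.41 in A12 cells and PPP1R13L by -0.06 and 8.28. In the same order ID1 changed by 8.79 and -0.62, BAHD1 by 7.84 and 0.80 and EIF2AK2 by 0.70 and 3.62. Without the parental vehicle day 8 array 1398 probes passed, since parental vehicle then rests on the day 5 array. Across genes, the oxLDL changes of A3 and A12 correlated at r = 0.318, and those of parental cells at day 8 correlated with the mean of the mutants at r = 0.246.

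Between day 5 and day 8, ribosomal protein genes fell as a list, with 25 of 28 members lower and a median of -0.27 (camera adjusted p = 0.000377, and 0.00122 with an estimated correlation). RPS3 (-0.63 ± 0.17) and RPL13 (-0.65 ± 0.23) passed neither adjustment. Cell cycle genes rose as a list, with 22 of 27 higher and a median of 0.58 (adjusted p = 0.000447, and adjusted p = 0.703 with an estimated correlation). MCM3 (2.36 ± 0.37) and CDC45 (0.94 ± 0.27) passed neither adjustment, and the cell cycle list did not pass without parental vehicle day 5 (adjusted p = 0.0611), parental oxLDL day 8 (0.170) or A12 oxLDL day 5 (0.107). By limma 1 probe fell, and it is the probe 878857 with no gene name here (-4.37 ± 0.28), singled out after its values were seen. It changed by -8.62 in A3 cells, and 609 probes had an unadjusted p under 0.05. Among genes that did not pass, ALOX12, SLC28A3, ENTPD4, MPI and NDUFB4 had the lowest p among higher values and CYP19A1, FRMD4A, DCDC2, FLOT1 and MARK3 among lower ones. ALOX12 changed by 4.49 in parental, -0.17 in A3 and -0.32 in A12 cells, SLC28A3 by 5.75 in parental and -1.98 in A3 cells and FRMD4A by -8.76 in A3 cells, and ENTPD4, NDUFB4 and DCDC2 were measured at both days in parental cells alone.

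Between the mutant lines A12 and A3, limma called 0 of 9382 probes, where 280 had an unadjusted p under 0.05. No gene list passed. ACAD8 (9.19 ± 0.62, adjusted p = 0.122) and DONSON (-3.43 ± 0.48, adjusted p = 0.122) had the lowest p in their directions, followed by ANKRD33B, TRANK1, ESRRA and NT5C2 among higher values and TMEM163, FOXP1, RPN2 and HOXB13 among lower ones.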

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

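The tests of ratio direction, of an exchange of arrays and of the cell cycle list without the parental vehicle day 5 array, and the comparison of spreads, were chosen only after their results were seen. The splits of the samples, the tests of values attached to other probes, the test of scaling and the test with an estimated correlation were written before their results were seen, apart from the use of an interval in the test of probe pairs, which was written with a doubt from the scanner table in mind.

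The response to PMA differed between mutant and parental lines at 426 probes by a test of the difference itself. By the same kind of test the NF-kB target genes (adjusted p = 0.000106), the scavenger and lipoprotein receptors (adjusted p = 0.0202) and the interferon response (adjusted p = 0.0367) differed in their response to PMA, and NF-kB target genes (adjusted p = 0.0139) and cell cycle genes (adjusted p = 1.10e-06) in their response to oxLDL. None of these lists passed with an estimated correlation, where the adjusted p were 0.239, 0.0577 and 0.180 for the response to PMA and 0.547 and 0.126 for the response to oxLDL. Without parental vehicle day 8 the lists for PMA did not pass (0.636, 0.213 and 0.692), and without parental vehicle day 5 the NF-kB list for oxLDL did not (0.940).

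The PMA-treated parental arrays other than vehicle day 5 ran against the mutant arrays, and the differences in the response to PMA rest on vehicle day 8 of these and on vehicle day 5. A turned ratio direction would make the oxLDL change of parental cells run against that of the mutants, and the correlation across probes was 0.246, which argues against it. Differences between mutant and parental lines spread 3.37 times as widely in vehicle-treated cells at day 8 as in unstimulated cells. Both a difference between parental and mutant macrophages and a different handling of those arrays may give this, and they cannot be told apart because the same arrays carry both. The scanner table raised the doubt that the reference channel of these 3 arrays differed from that of the others. This was not tested, since no scanner column entered a comparison here.

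The parental vehicle day 5 array was unlike every other array. The scanner table, whose columns carry no sample name and entered no comparison here, raised the doubt that the values of this array sit on other probes. An exchange with another array of the series would leave a high correlation with some array, and the highest absolute value was 0.0877. Values attached to other probes could give such correlations, and 2 bounds written in advance against this were met, though neither decides it. The first, an SD outside the range of 0.995 to 1.73 of the other arrays, was met at 1.88, but giving values to other probes leaves their SD as it was. The second was met at r = 0.0538 between probes of 1 gene (409 pairs, 95% interval -0.0434 to 0.15; other arrays 0.0453 to 0.180), but the interval, applied after this value was seen, holds the 0 that misplaced values would give, so the explanation stays open.

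Cell cycle genes had lower changes with oxLDL in the mutants than in parental cells at the preset correlation. The parental vehicle day 5 array is not needed for this, since the adjusted p was 6.04e-06 without it, and neither is the scale of the arrays, with an adjusted p of 0.0023 after scaling. Without parental vehicle day 8, where parental vehicle rests on the day 5 array, it was 0.135. Members moving together could account for it, since the adjusted p was 0.126 with an estimated correlation. A difference between the lines in how oxLDL acts on the cell cycle stays open and untested.

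For the 24 probes that passed with oxLDL, 1 of 32 splits that exchange vehicle and oxLDL within line and day gave as many, the real one, and the highest other gave 4, so chance was excluded at the share of 0.05. For mutants against parental, 1 of 100 splits gave as many as the real 2635 and the highest other gave 4. These splits exchange single arrays between lines, and there is 1 parental line. They therefore exclude neither a chance difference between lines nor an effect of the handling of the arrays. For PMA, 7 of 27 splits gave at least the real 2, with a highest other of 15, which may reflect a structure of the samples that was not tested. For day, 16 of 32 gave at least the real 1, with a highest other of 4. For PMA and for day, exchanged labels alone could give the count, so chance was not excluded there either. For A12 against A3 the 16 splits are too few for a share under 0.05; the real count was 0 and the highest other 0.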

How the results depend on the processing

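The alternatives with the parental PMA term, which also leave out the doubtful parental vehicle day 5 array, with the sign turned, with probes on all or on at least 10 arrays, with a robust variance prior, with pairs of arrays and with unstimulated cells only were chosen after their results or the data were seen. Background correction, loess, print-tip loess, average-intensity quantile scaling, the filter on dim probes and the intensity trend were not run, since intensities were not used here. The cause of the changes below was not tested, except that leaving out lines or arrays leaves fewer samples. Over all alternatives, counts of probes or of lists stayed the same or within 1.5 times in 249 cases and moved further in 140. The 249 include counts that were 0 in both fits, as in most alternatives for A12 against A3. Named genes and lists kept their direction and side of the threshold in 5444 cases, fell short of it in 450, passed it in 169, had the opposite sign in 41 where 1 of the fits had passed and in 187 where neither had. The 5444 include genes that passed in neither fit, so these tallies do not measure how stable the calls were.

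The count for oxLDL, 24, became 38 with scaling, 617 with array weights, 389 without the parental line, 0 without the A3 line, 0 without the A12 line, 0 with day 8 pairs alone, 58 with a mean per line and state, 382 with the parental PMA term and without the doubtful array, 391 with that and probes on at least 10 arrays, and 2 with the sign turned. The count for PMA, 2, became 1 with scaling, 24 with array weights, 114 with a mean per line and state, 11 and 18 with the parental PMA term, where it rests on the mutant lines, and 0 by limma with gene means, without any 1 line or with probes on all arrays (645; 889, 538 and 529; and 361 at an unadjusted p under 0.05). The count for day, 1, became 62 with array weights, 11 and 23 with the parental PMA term, 2 with the sign turned, and 0 with gene means, without any 1 line, with a mean per line and state, with pairs of arrays (708 at an unadjusted p under 0.05) or with probes on all arrays. A12 against A3 went from 0 to 1 with array weights.

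The count for mutants against parental, 2635, became 4793 with array weights, 1545 with A3 alone, 4904 with line as a random block (whose estimated correlation was -0.154), 3 with the parental PMA term, which takes up the difference in PMA-treated cells by construction and so leaves that in unstimulated cells, 1554 with probes on all arrays, 271 with the sign turned and 0 in unstimulated cells. Higher and lower probes, 1127 and 1508, became 1705 and 1506 with scaling. In oxLDL-loaded cells 2519 became 1305 with probes on all arrays and 589 with the sign turned, and the 987 higher and 1532 lower became 1298 and 1301 with median centring and 1453 and 1444 with scaling. The difference in the response to PMA, 426, became 8 with array weights, 676 with genotype by state, 931 without the doubtful array, since the term does not enter this fit, 205 with probes on all arrays and 23 with the sign turned. The difference in the response to oxLDL went from 0 to 4 with the sign turned.

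Gene lists that passed went from 5 to 3 with PMA, 3 to 1 with oxLDL, 2 to 0 for mutants, 2 to 1 for day, 2 to 0 and 3 to 0 for the differences in response to oxLDL and PMA and 2 to 0 in oxLDL-loaded cells with an estimated correlation. With fry, on probes measured on all arrays only, they were 0 with PMA, 12 for mutants, 1 for day, 0 for the response to oxLDL, 7 for the response to PMA and 14 in oxLDL-loaded cells. Test and list members both differ there from those of camera. Without the doubtful array and with the parental PMA term 8 passed with oxLDL and 0 for mutants, and without that array alone 5 passed with oxLDL and 1 for the response to oxLDL, with gene means 6 passed with oxLDL, and with pairs of arrays 5 passed with oxLDL. With the sign turned 2 passed for PMA, 1 for day, 6 for the response to oxLDL and 0 for the response to PMA.

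With the parental PMA term, mutants against parental rests on the 1 unstimulated parental array, so values of the other sign there are not turned directions of the same comparison. They were those of RGPD1 (-0.021), MED15 (-0.42), MYO9A (-0.44), CALCOCO1 (-0.34), BCL2L11 (-0.12), FABP3 (-0.48), OR7E47P (0.48), PLIN2 (0.84) and CD36 (1.06), and the NF-kB and interferon lists had the other sign too (adjusted p = 0.558). MYO9A, CALCOCO1, BCL2L11, FABP3, OR7E47P, PLIN2 and CD36 had these values in unstimulated cells too. With the sign turned, the NF-kB and interferon lists turned for mutants (adjusted p = 0.772) and the NF-kB list for the response to PMA (adjusted p = 0.939), as did BCL2L11 (-0.47), TRIM15 (-2.10) and NFKBIA (-0.62) for mutants and NFKBIA (-1.64) for the response to PMA. In oxLDL-loaded cells BCL2L11 (-0.75), TRIM15 (-3.62), IL1B (-0.63), NFKBIA (-0.37), PLIN2 (0.50), MSR1 (0.62) and CD36 (0.86) turned with it.

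Leaving out 1 array at a time gave between 0 and 18 probes for PMA, 0 and 118 for oxLDL, 707 and 3978 for mutants, 0 and 13 for day, 0 and 1398 for the response to oxLDL, 140 and 1334 for the response to PMA and 1047 and 3379 in oxLDL-loaded cells. Without parental vehicle day 8 the response to oxLDL gave 1398, since parental vehicle then rests on the day 5 array, the response to PMA 1334, mutants 769 and PMA 0. Without parental vehicle day 5 oxLDL gave 37, PMA 5, day 6 and the response to PMA 931. Without unstimulated parental cells oxLDL gave 118, mutants 3978, PMA 5 and day 2. Without parental oxLDL day 8 oxLDL gave 0, PMA 0, mutants 707, the response to PMA 194 and oxLDL-loaded cells 1047, and without parental oxLDL day 5 mutants gave 993, PMA 1, day 4, the response to PMA 196 and oxLDL-loaded cells 1146. Of the A3 arrays, oxLDL gave 2, 1 and 5 without vehicle day 8, oxLDL day 5 and oxLDL day 8, PMA gave 0 without vehicle day 8, 1 without oxLDL day 5 and 18 without unstimulated cells, mutants 1724 without oxLDL day 8, and day 0 without vehicle day 8. Of the A12 arrays, oxLDL gave 3, 4 and 1 without vehicle day 8, oxLDL day 5 and oxLDL day 8, PMA 1, 8 and 1 without unstimulated cells, vehicle day 5 and oxLDL day 8, and day 13 and 0 without vehicle day 5 and oxLDL day 5. The response to PMA gave 197, 192, 219 and 239 without the A3 arrays of vehicle day 5, vehicle day 8, oxLDL day 5 and oxLDL day 8, and 179 and 140 without the A12 vehicle arrays. NFKB1 turned in its response to PMA without parental vehicle day 8 (-1.86), and over the arrays left out its values reached 2.91. Lists passing ranged from 1 to 6 for PMA, 2 to 7 for oxLDL, 1 to 2 for mutants, 1 to 3 for day, 1 to 4 and 0 to 4 for the responses to oxLDL and PMA and 1 to 5 in oxLDL-loaded cells. Unstimulated arrays could not be left out of the response to PMA.

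The labels give no numbers that pair arrays. With a term for each of the 6 pairs of vehicle and oxLDL arrays of a line and day, and 5 residual degrees of freedom, the 24 probes for oxLDL became 16, 6 of the 24 among them.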

Other observations

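Other gene groups were examined with oxLDL and did not pass as lists. Targets of LXR, which drive cholesterol efflux, had 7 of 9 members higher and a median of 0.57 (camera adjusted p = 0.0703), and LPL changed by 2.51 ± 0.79 (adjusted p = 0.261). The list of PPAR targets and lipid storage had a camera adjusted p of 0.0893, and CPT1A (1.61 ± 0.35), FABP4 (0.98 ± 0.30) and ACSL1 (1.90 ± 0.68) rose and PLIN3 (-0.55 ± 0.17) fell when adjusted over the list alone. Among 10 heat shock genes 3 rose, HSPA6 (1.92 ± 0.41) and HSPA1B (1.37 ± 0.39) among them, and HSPB1 (-2.17 ± 0.46) fell when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.508). Endothelial, fibroblast and lymphocyte markers did not pass with oxLDL (camera adjusted p of 0.360, 0.673 and 0.583). For mutants against parental, 7 of 7 tested endothelial markers were higher and 2 passed over all probes, while the list did not pass (camera adjusted p = 0.172). In oxLDL-loaded cells 5 of 5 were higher and 2 passed, and the list did not pass either (camera adjusted p = 0.0646).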
